A study of Mus musculus with 4 samples.

How the data were processed

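Cells of Nestin-GFP and doublecortin-mRFP mouse embryos were dissociated from cortex or ganglionic eminence (GE) and sorted for green fluorescence, per the labels' protocols. Droplet libraries of 3' ends were made with the 10x Genomics v2 chemistry, with about 10000 cells loaded, per the labels' protocols. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 1.3.1 on the mm10 build, per the submitters' processing notes. Those notes also name Seurat, without a version or a setting. All deposited values were checked to be whole numbers. The annotation release, the rule for calling cells, and the number and sex of the embryos pooled are not given in the sources used here. The files pair 27998 gene identifiers with symbols, 56 of the symbols belonging to more than 1 identifier, and those genes were kept apart by identifier. Positions of the genes printed with coordinates come from GENCODE M21 on GRCm38 (mm10).

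The labels put the 4 libraries in 4 groups, cortex or GE at E15.5 or E18.5, with 1 library each. Groups follow the labels, although the names of the deposited files give the other region for every library. Barcodes with fewer than 1000 detected genes or more than 10% of UMIs from the 13 mitochondrially encoded genes were left out, which removed 2, 35, 3 and 5 barcodes of the libraries labelled cortex E15.5, cortex E18.5, GE E15.5 and GE E18.5. Doublet-like barcodes were scored within each library against 2 simulated doublets per barcode, and the top 0.8% per 1000 barcodes of the library were left out, which removed 11, 79, 6 and 11. The cells kept hold 28770160, 27739574, 30651253 and 14229776 UMIs.

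Kept cells of all libraries were clustered together. Counts were scaled to the median depth and log-transformed, 2000 variable genes were standardised and limited to 10, and 30 principal components gave a shared neighbour graph of 20 neighbours. Leiden communities at resolution 1 gave the clusters. Each cluster took the class with the highest mean log2 fold of its fixed markers over the other cells, with 10 CPM added to each side. Markers counted if they were at least 1.5-fold higher and found in at least 10% of the cluster's cells, and at least 3 were needed. A lead of at least 0.1 over the next class was also needed, and no other class could have more markers among the cluster's top 10 genes. This lead, and the removal of haemoglobin genes from the scores, were set after seeing the data. No batch correction was used, since each library is its own group.

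UMIs were summed over the kept cells of a library and divided by its total to give counts per 1000000 (CPM). The totals left out the 13 mitochondrial genes, 86 ribosomal protein genes and 10 haemoglobin genes, and were 22370416, 22341004, 23073873 and 11430139 UMIs. A gene was measured in a comparison if it had at least 20 CPM in at least 1 of the 2 libraries, and was called higher or lower if the ratio was at least 2-fold with a 95% interval that excludes 1. Counts of genes require the same direction in both labelled regions, or at both ages. The same was done for the cells of radial glia-like and astrocyte lineage-like clusters, pooled because the classes grade into each other. Ratios of expression carry exact conditional binomial intervals, CPM exact Poisson intervals, and shares exact Clopper-Pearson intervals. With 1 library per group no test between groups was made, and cells were not used as replicates. A share of 0 cells carries the limit that 3 counts allow. Against a library at 0, a ratio was taken to 3 counts and is a bound. Such a bound was left out where it fell on the other side of 1 and so said nothing, a rule set after seeing the data.

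The genes named were set by a rule fixed before the data were examined. For each of the 4 gene comparisons they are the 10 higher and 10 lower genes with the largest smaller-of-2 absolute log2 ratio, without predicted genes lacking a name and without Xist, Tsix and 4 Y-linked genes. From each fixed list up to 4 members with the largest absolute log2 ratio may be named. Nes, Dcx, Sparc, Sparcl1, Emx1, Dlx2, Hmga2, Aqp4, Olig2 and Mki67 were named in any case. The 30 fixed lists cover dorsal and ventral patterning, astrocyte and oligodendrocyte lineage, gliogenic factors, early temporal genes, radial glia and Notch, neurogenic progenitors, neuron differentiation, S phase, G2 and M phase, BMP and ID, gp130 and STAT, FGF with EGF and ERK, Hedgehog, extracellular matrix, cholesterol synthesis, dissociation and immediate early genes, interferon and MHC, glycolysis and hypoxia, regional position, and the reporter genes. The other 8 hold markers of endothelial, mural, fibroblast, microglial, erythroid, choroid plexus, ependymal and Cajal-Retzius cells. Some genes stand in more than 1 list. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test.

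Sparc and Sparcl1 were read in pooled glial cells thinned at random to 5000 UMIs, the largest of the depths tried that keeps at least 80% of these cells in every library (83.8% of those labelled cortex E18.5). Cells with fewer UMIs were left out. Detection is 1 UMI or more. The ratio of joint to independent detection was first given the exact interval of the joint share over an expected share held fixed. After seeing the data, an interval from 10000 draws of resampled cells was added for sets of at least 100 cells, which varies both shares. Ratios of genes between Sparc-only and Sparcl1-only cells used the same rules and had to hold in both E18.5 libraries.

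The scripts were tested on simulated counts drawn from the libraries' own means, with 200 genes given known folds. In the comparison by age in all cells, 100 of 100 genes were recovered at 2.5-fold and at 4-fold, among 6741 genes, and likewise by region among 6675. In pooled glial cells by age, 83.2% of the genes tested were recovered at 2.5-fold and 100% at 4-fold among 7214, and by region 83.7% and 97.0% among 6752. No unchanged gene was called in these 4. For Sparc-only against Sparcl1-only cells 66.3% and 94.0% were recovered, and 1 unchanged gene was called among 7327. The simulated counts vary by counting error alone.

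Alternatives tried were TMM and DESeq2 scaling, minimums of 5 and 100 CPM and none, 1.5-fold and 3-fold thresholds, and no cell filter or a filter of at least 2000 genes and at most 5% mitochondrial UMIs. Further ones were doublet-like barcodes kept, the mean of each cell's CPM, thinned cells, other Leiden resolutions (0.5 and 2), vascular, blood and immune clusters left out, and radial glia-like clusters only. For Sparc and Sparcl1 they were unthinned cells, 2000 UMIs, and detection at 2 UMIs. Leaving out barcodes with more than 2 times their library's median UMIs was added after seeing the data, as was a comparison of list medians over genes measured in both labelled regions. Sequence reads were not used here, and results of a few genes, with the microglial list, were left out of the text. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.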

Results

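Single-cell RNA sequencing was carried out on cells of mouse embryos that carry a Nestin-GFP and a doublecortin-mRFP reporter. Nestin (Nes) marks neural stem and progenitor cells, and doublecortin (Dcx) marks young neurons. Cells with green fluorescence were sorted from dissociated cerebral cortex or ganglionic eminence (GE), the ventral forebrain region that produces GABAergic interneurons and striatal neurons, on embryonic day E15.5 or E18.5. Each of the 4 groups, 2 regions at 2 ages, held 1 library, so no difference below has a replicate check and none was tested. The title and design of the series ask which progenitor types exist while neurons and then glia are made, and whether astrocyte lineages diverge.

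The library labelled cortex E15.5 held 1170 barcodes and 29255083 unique molecular identifiers (UMIs), and that labelled cortex E18.5 held 3139 barcodes and 29427527 UMIs. The library labelled GE E15.5 held 879 barcodes and 31173997 UMIs, and that labelled GE E18.5 held 1153 barcodes and 14528712 UMIs. After filtering, 1157, 3025, 870 and 1137 cells were kept in the same order, with medians of 16249, 8660, 23219 and 10085 UMIs per cell. The poorest barcode held 10407 UMIs in the library labelled cortex E15.5 and 11667 in that labelled GE E15.5, against 2676 and 4064 in the libraries labelled E18.5. The rule by which barcodes were called as cells is not given in the sources used here. Brackets give 95% intervals, which cover counting error only.

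The region in the labels and the region in the names of the deposited files are opposite for all 4 libraries, so genes of the dorsal and ventral forebrain were read first. Emx1 (ENSMUSG00000033726), a transcription factor of cortical progenitors, had 29 UMIs or 1.296 counts per 1000000 (CPM) in the library labelled cortex E15.5 and 6419 UMIs or 278 CPM in that labelled GE E15.5. Nkx2-1, which specifies the medial ganglionic eminence, had 269 CPM in the library labelled cortex E15.5 and 0.997 CPM in that labelled GE E15.5. All 13 measured genes of the dorsal patterning list were lower in the library labelled cortex at E15.5, with a median log2 ratio to the library labelled GE of -6.08. At E18.5, 8 of 10 dorsal genes were lower there, with a median of -3.92. All 16 measured genes of the ventral patterning list were higher in the library labelled cortex at E15.5 (median 5.21), as were 11 of 14 at E18.5 (median 1.82). The region named for each library below is its label, which these genes go against at both ages. An exchange at both ages would leave each comparison of ages within 1 tissue and would turn every comparison of regions round.

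**Figure D1:**
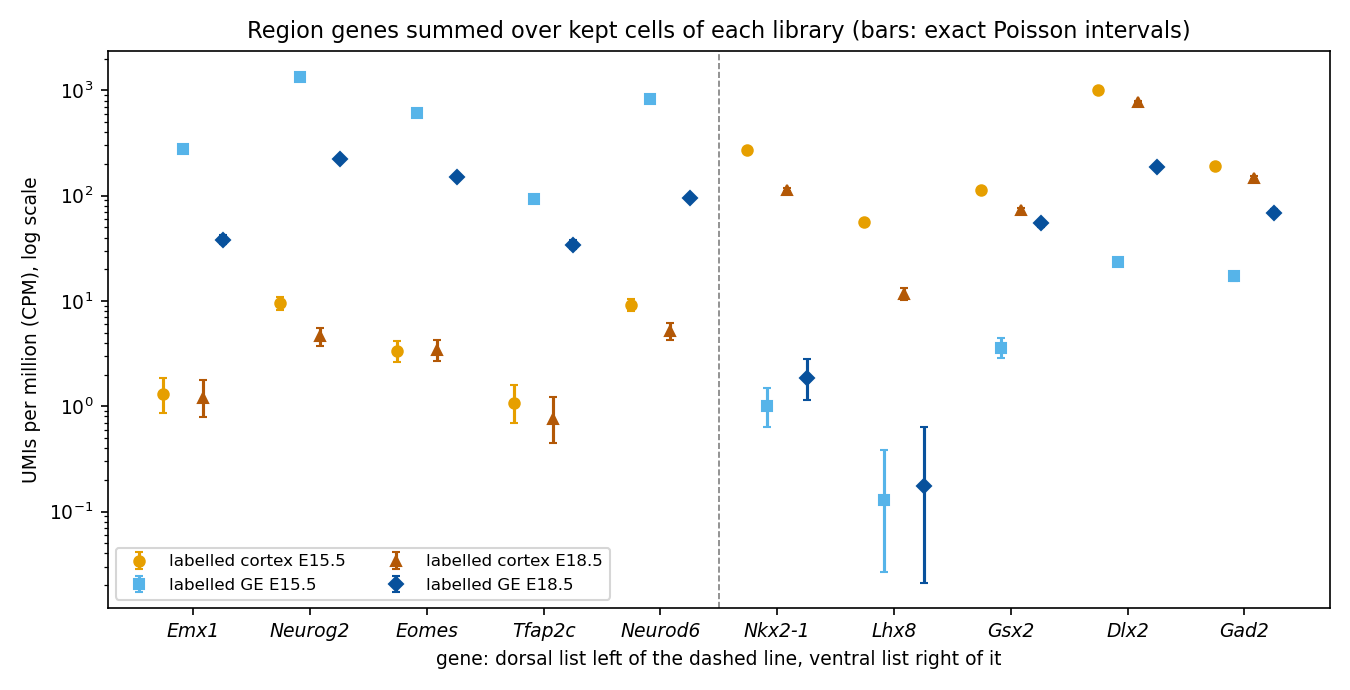
Counts per 1000000 UMIs (CPM, log axis) of 5 genes of the dorsal and 5 of the ventral forebrain in the 4 libraries, with exact Poisson 95% intervals. Emx1 lies at 1.296 CPM in the library labelled cortex E15.5 and at 278 CPM in that labelled GE E15.5.

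The reporter genes differed less between libraries. Nes (chromosome 3, 87971078 to 87980451 in GRCm38) had 77.9 and 93.4 CPM in the libraries labelled cortex E15.5 and E18.5, and 107 and 166 CPM in those labelled GE. Dcx (chromosome X, 143855842 to 143933311) had 236, 204, 317 and 199 CPM in the libraries labelled cortex E15.5, cortex E18.5, GE E15.5 and GE E18.5. Neither gene reached a 2-fold difference with age or between labelled regions.

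Clustering of all 6189 kept cells gave 21 clusters, of which 18 could be named after a cell class by fixed marker genes. The sort on the Nestin reporter sets which cells are present, so the shares describe sorted cells. Cell calling may set them too, since no barcode of the E15.5 libraries held under 10407 UMIs. GE intermediate progenitor-like cells made up 51.4% (48.5 to 54.3) of the library labelled cortex E15.5 and 45.8% (44.0 to 47.6) of that labelled cortex E18.5, but 0.805% and 7.48% of those labelled GE. This class held clusters 1, 8, 9, 10 and 12. The top 10 genes of clusters 8, 10 and 12 were mostly histone and cell division genes, with 0 class markers. In the libraries labelled cortex E15.5 and E18.5, cluster 9 held 291 and 48 cells and cluster 8 held 5 and 362. The class thus partly gathers dividing cells and compares different clusters at the 2 ages. Cortical intermediate progenitor-like cells made up 16.2% of the library labelled GE E15.5 and 4.93% of that labelled GE E18.5. In the library labelled cortex E15.5 there were 0 of 1157 such cells, which allows a share of up to 0.259%, and in that labelled cortex E18.5 the share was 0.0992%. Excitatory neuron-like cells made up 10.0% and 1.93% of the libraries labelled GE, and 0.259% and 0.331% of those labelled cortex. GABAergic neuron-like cells made up 3.54% and 21.6% of the libraries labelled cortex E15.5 and E18.5, and 0.115% and 13.5% of those labelled GE. Cluster 7, with 384 cells labelled cortex E15.5, scored highest for this class but stayed unnamed, so the change with age depends on naming. At E18.5 the GABAergic neuron-like cells came mostly from different clusters. Cluster 5 held 398 and cluster 16 held 35 cells labelled cortex, against 10 and 132 labelled GE.

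Glial classes had larger shares in both E18.5 libraries. Clusters 3, 4 and 6, of the oligodendrocyte and astrocyte lineage-like classes, had medians of 9218.5, 8877 and 8872 UMIs, mostly over E18.5 cells. These medians lie under the poorest E15.5 barcode, with 10407 UMIs. Cell calling may thus add to the differences in share with age, which was not tested. Astrocyte lineage-like cells made up 2.07% (1.33 to 3.07) of the library labelled cortex E15.5 and 20.3% (18.9 to 21.8) of that labelled cortex E18.5. In the libraries labelled GE their share was 0.230% (0.0279 to 0.828) at E15.5 and 19.2% (16.9 to 21.6) at E18.5. This class held clusters 4 and 6, and the libraries filled them unevenly. Cluster 4 held 251 cells and cluster 6 held 363 in the library labelled cortex E18.5, against 180 and 38 in that labelled GE E18.5. In cluster 6 astrocyte markers had a mean log2 fold of 2.06 and ependymal markers came next at 1.67, so similar shares hold different mixes. Oligodendrocyte lineage-like cells made up 0.432% and 5.62% of the libraries labelled cortex E15.5 and E18.5, and 0.460% and 25.9% (23.4 to 28.6) of those labelled GE. Radial glia-like cells made up 10.9% and 18.03% of the libraries labelled GE E15.5 and E18.5, and 0.173% and 0.562% of those labelled cortex. The split between radial glia-like and astrocyte lineage-like cells shifted with the clustering settings, as given below. Of the 40 shares, 16 moved with cells thinned before clustering. Nearly all radial glia-like cells came from 1 cluster per age, since cluster 18 held 94 cells of the library labelled GE E15.5 and cluster 13 held 198 of that labelled GE E18.5, so this class compares different clusters at the 2 ages.

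Mural cell-like barcodes (pericytes and vascular smooth muscle) made up 1.49% and 1.32% of the libraries labelled GE E15.5 and E18.5, and 0.231% of that labelled cortex E18.5. In that labelled cortex E15.5 there were 0 of 1157, which allows a share of up to 0.259%. This cluster had a mean log2 fold of 5.90 for mural and 4.45 for endothelial markers. The endothelial markers Cldn5 and Igfbp7 were among its top 10 genes, so it may mix vascular cell types. Microglia-like barcodes numbered 1, 2, 3 and 0 in the libraries labelled cortex E15.5, cortex E18.5, GE E15.5 and GE E18.5. Clusters 2, 7 and 11 stayed unnamed, clusters 2 and 7 because no class had a clear lead. Cluster 7 scored 0.63 for GABAergic neuron and 0.53 for GE intermediate progenitor. Cluster 2 scored 1.48 for cortical excitatory neuron and 1.47 for cortical intermediate progenitor. Cluster 11 scored best for radial glia, with 8 markers detected, but more of its top 10 genes were oligodendrocyte lineage markers. It held 99 and 152 cells labelled cortex E15.5 and E18.5, and 3 and 64 labelled GE. These cells are not in the radial glia-like shares above, which depend on this naming rule. The unnamed clusters held 42.0% and 59.4% of the libraries labelled cortex E15.5 and GE E15.5, and 5.45% and 7.65% of those labelled cortex E18.5 and GE E18.5. Cluster 2 held 514 cells of the library labelled GE E15.5 and cluster 7 held 384 of that labelled cortex E15.5, so most of their cells came from 1 library each. These cells count in the totals of the shares above but in none of the named classes. The E15.5 shares of the classes they scored for could thus be larger under another rule, and their changes with age depend on it. Many of the E15.5 barcodes in clusters 2 and 7 carried both Xist and Y-linked UMIs, as given at the end. Some may hold more than 1 cell.

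**Figure D2:**
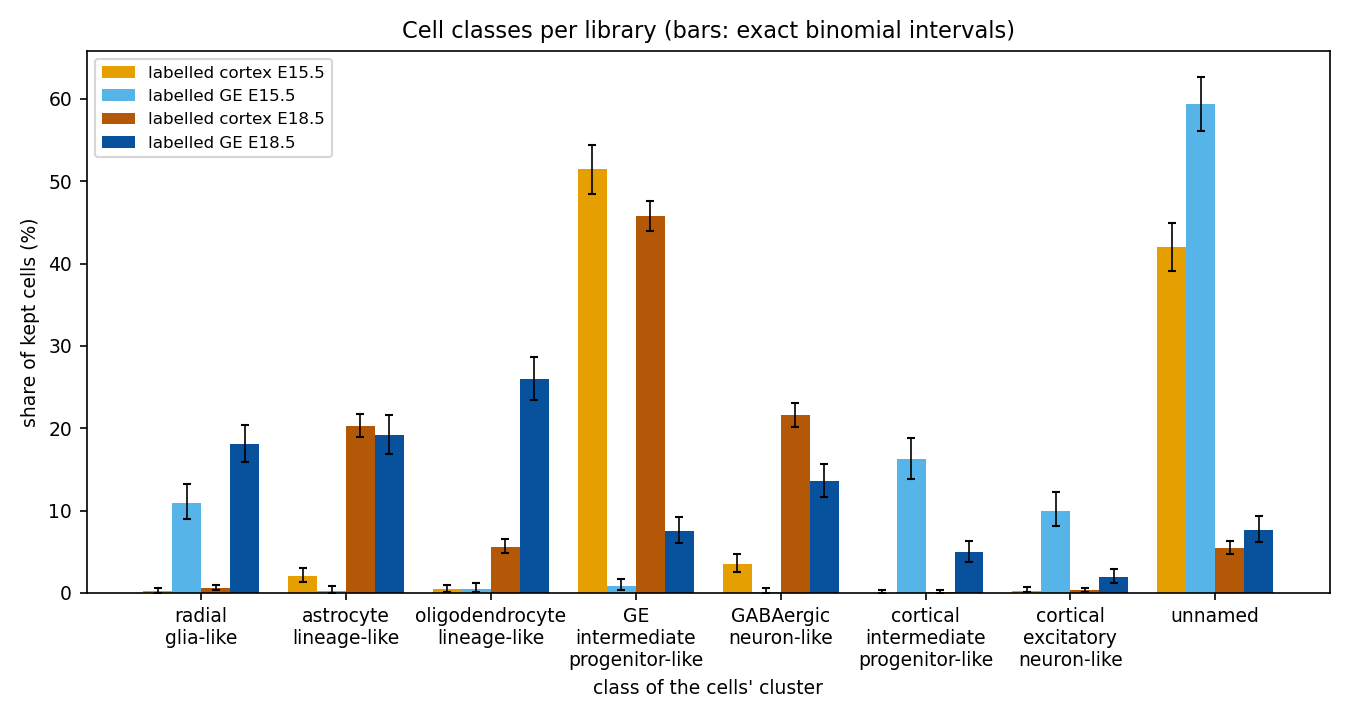
Share of kept cells (%) in each cell class in the 4 libraries, with exact binomial 95% intervals. Astrocyte lineage-like cells make up 20.3% and 19.2% of the libraries labelled cortex E18.5 and GE E18.5, and unnamed clusters 42.0% and 59.4% of those labelled cortex E15.5 and GE E15.5.

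Expression at E18.5 was compared with that at E15.5 in each labelled region, to see which genes mark the later, gliogenic age. Astrocyte genes were among the 10 that led the genes higher in both labelled regions, ranked by the smaller of the 2 ratios. Aqp4 (ENSMUSG00000024411), the water channel of astrocyte endfeet, was 63.4-fold (34.2 to 133) higher at E18.5 in the libraries labelled cortex and 29.5-fold (19.3 to 47.2) higher in those labelled GE. Apoe, which encodes the main lipid carrier secreted by astrocytes, was 16.3-fold (15.7 to 17.1) and 17.0-fold higher. Sparcl1 (ENSMUSG00000029309), a secreted matricellular protein, was 22.1-fold (18.8 to 26.1) and 11.6-fold (10.7 to 12.6) higher. The thyroid hormone transporter gene Slco1c1 was 59.4-fold and 25.5-fold higher, and the phospholipase gene Pla2g7 16.9-fold and 20.2-fold. Slc6a11, Emp2, Ramp1, Hepacam and Luzp2 completed the 10, from 8.84-fold to 36.0-fold. In the libraries labelled GE some of these sizes depend on processing. With cells thinned to 1 depth the log2 ratio of Aqp4 was 6.75 in place of 4.88, that of Hepacam 7.08 in place of 5.17 and that of Ramp1 3.28 in place of 4.12. Without vascular, blood and immune clusters that of Sparcl1 was 4.32 in place of 3.54, and by the mean of cells that of Slco1c1 was 4.05 in place of 4.67.

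Among 7122 genes measured in both regions, 234 were at least 2-fold higher at E18.5 in both and 9 were lower in both. No gene was higher with age in one labelled region and lower in the other. In single regions, 314 genes were higher and 31 lower among 7335 in the libraries labelled cortex, and 682 higher and 210 lower among 7913 in those labelled GE. Scaling by edgeR's trimmed mean of M values (TMM) moved every log2 ratio by -0.14 in the libraries labelled cortex and by -0.18 in those labelled GE. Relative to that shift, 170 genes were higher and 13 lower in both. The share of astrocyte lineage-like cells was also higher at E18.5 in both labelled regions, so these ratios of whole libraries move with the mix of cells.

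The 9 lower genes included 4 haemoglobin genes. Hbb-bt was 94.5-fold lower at E18.5 in the libraries labelled cortex and 81.7-fold lower in those labelled GE, and Hba-a1 was 39.8-fold and 104-fold lower. In the library labelled cortex E15.5, 1 barcode held 10938 of the 11127 kept haemoglobin UMIs, and in that labelled GE E15.5 1 barcode held 14268 of 14652. Hbb-bs and Hba-a2 were lower in both as well, from 34.3-fold to 339-fold. With all barcodes kept, neither filtered nor freed of doublet-like ones, the log2 ratio of Hbb-bt was -1.70 in the libraries labelled cortex and 0.24 in those labelled GE, and that of Hba-a1 -0.39 and 0.46, so the direction turned in those labelled GE. Among genes of neural cells, Lmo1, a transcriptional cofactor of forebrain progenitors, was 3.16-fold (3.03 to 3.31) and 2.75-fold (2.53 to 2.99) lower. Nr2f1, which patterns cortical areas, was 2.27-fold (2.18 to 2.36) and 2.19-fold (2.09 to 2.28) lower. The collagen gene Col2a1 was 2.65-fold and 2.39-fold lower, and the centrosomal gene Akna 2.29-fold and 2.27-fold. The remaining gene is a predicted one without a name. With the deepest barcodes of each library left out, an alternative chosen after seeing the data, 1 gene was lower in both labelled regions, Lmo1 at -1.75 and -1.63. Nr2f1 then had -1.01 and -0.80, and the predicted gene -0.92 and -1.51. Akna had -0.76 in the libraries labelled cortex and Col2a1 -1.25 in those labelled GE, each being under the CPM minimum in the other. The haemoglobin genes stayed lower in those labelled GE. In those labelled cortex they were under the minimum, with log2 ratios above 0, from 0.08 for Hbb-bt to 0.81 for Hba-a1. With the deep barcodes in, these 2 had -6.56 and -5.31.

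Of 24 measured astrocyte lineage genes, 23 were higher at E18.5 in the libraries labelled cortex (median log2 ratio 2.53) and 21 in those labelled GE (median 2.45). Pla2g7 and Apoe led this list beside Aqp4, with log2 ratios of 4.08 and 4.03 in the libraries labelled cortex. Both medians lay at percentile 100 of 10000 random lists of genes of like expression, as did those of the extracellular matrix list in both labelled regions. Genes of the extracellular matrix were higher in 7 of 10 (median 2.01) and 10 of 11, with 1 lower (median 2.39), and they included Sparcl1, Tnc and Bcan. Sparc (ENSMUSG00000018593), the collagen-binding relative of Sparcl1, had log2 ratios of 1.72 and 1.17, the latter falling under 2-fold by the mean of cells (0.47) and without the deepest barcodes (0.54). Of the oligodendrocyte lineage genes, 3 of 5 were higher in the libraries labelled cortex (median 1.42) and 10 of 10 in those labelled GE (median 4.04). Olig1, a transcription factor of that lineage, had log2 ratios of 2.53 and 5.29. Its relative Olig2 (chromosome 16, 91225457 to 91228677) had log2 ratios of 0.68 and 5.23. The list of radial glia and Notch genes had 6 of 19 higher (median 0.54) and 12 of 19 higher (median 1.18), with the glutamate transporter gene Slc1a3 at 2.24 and 1.97. Gliogenic transcription factors were higher for 1 of 13 genes, Etv5 at 1.52 (list median 0.68), and for 8 of 15, with 1 lower (median 1.11), Olig2, Sox8 and Etv4 foremost.

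In the list of FGF, EGF and ERK response genes, 3 of 8 were higher at E18.5 in the libraries labelled cortex (median 0.39) and 9 of 12 in those labelled GE (median 2.08). Egfr, the EGF receptor of late progenitors, had log2 ratios of 1.98 and 6.54, and the ERK feedback inhibitor gene Spry2 had 2.03 and 3.21. Cholesterol synthesis genes were higher for 2 of 17 (median 0.77) and 9 of 18 (median 0.98), including Hmgcs1 at 1.15 and 1.73. BMP and ID response genes were higher for 2 of 6 in each (medians 0.93 and 0.33), Id3 at 1.88 and 4.21 and Id1 at 1.28 and 2.23. In the interferon and MHC list 3 of 5 and 2 of 4 were higher, with Ifitm3 at 3.34 and 2.26. The list of gp130 and STAT response genes had 1 and 2 measured members, and Stat3 was higher in the libraries labelled GE at 1.04. Mural genes were higher for 1 of 2 (Pdgfrb, 1.89) and 4 of 5 (median 1.46).

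The neurogenic progenitor list had 0 of 10 genes past 2-fold in the libraries labelled cortex (median -0.24), and in those labelled GE 8 of 16 were lower and 3 higher (median -1.19). Neurog1, a proneural factor of cortical progenitors, had a log2 ratio of -6.95 there, and the neuronal factor Nhlh1 had -3.72. Neuron differentiation genes had 0 of 16 past 2-fold, and 4 of 19 higher and 3 lower. None of the 20 G2 and M phase genes passed 2-fold in the libraries labelled cortex (median -0.60) or in those labelled GE (median -0.12), and Mki67 (chromosome 7, 135689784 to 135716361) had 0.29 and 0.96. None of 20 and 19 S phase genes did either. Early temporal radial glia genes were lower for 3 of 9 in the libraries labelled cortex (median -0.56), namely Crabp2 at -2.64, the chromatin gene Hmga1 at -1.72 and the RNA-binding gene Igf2bp1 at -1.22. In those labelled GE 4 of 10 were higher, with Igf2 at 3.38, and 1 was lower, with no direction of the median that held under scaling. Hmga2 (chromosome 10, 120361275 to 120476469) stayed under the minimum of 20 CPM in every library.

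Genes of position and stress went several ways. Regional position genes were lower for 2 of 11 (median -0.52) and 5 of 12 (median -0.50), with Nr2f1 and Fezf2 among them, and Rlbp1 was higher at 2.15 and 1.62. Dorsal patterning genes had 0 of 3 past 2-fold in the libraries labelled cortex, and 11 of 13 were lower in those labelled GE (median -2.02). Ventral patterning genes were lower for 2 of 16, Lhx8 at -2.26 and Nkx2-1 at -1.23, and higher for 9 of 9 in those labelled GE (median 2.56). Hedgehog response genes were higher for 1 of 5 (Gas1, 1.34), and in those labelled GE 1 was higher (Ptch1, 2.10) and 1 lower (Boc, -1.05) of 7. Glycolysis and hypoxia genes were higher for 1 of 11 (Aldoc, 2.57), and in those labelled GE 3 were higher and 1 lower of 14. Of the immediate early genes that dissociation induces, 2 of 8 were higher in each, Fos at 2.03 and 1.28 and Egr1 at 1.86 and 1.41. The endothelial list had 0 measured members in the libraries labelled cortex, and 1 of 4 was lower in those labelled GE (Cldn5, -1.20). The choroid plexus list had only Enpp2 measured, in those labelled GE (4.19). Fibroblast, ependymal and Cajal-Retzius neuron lists had no measured member in whole libraries.

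**Figure D3:**
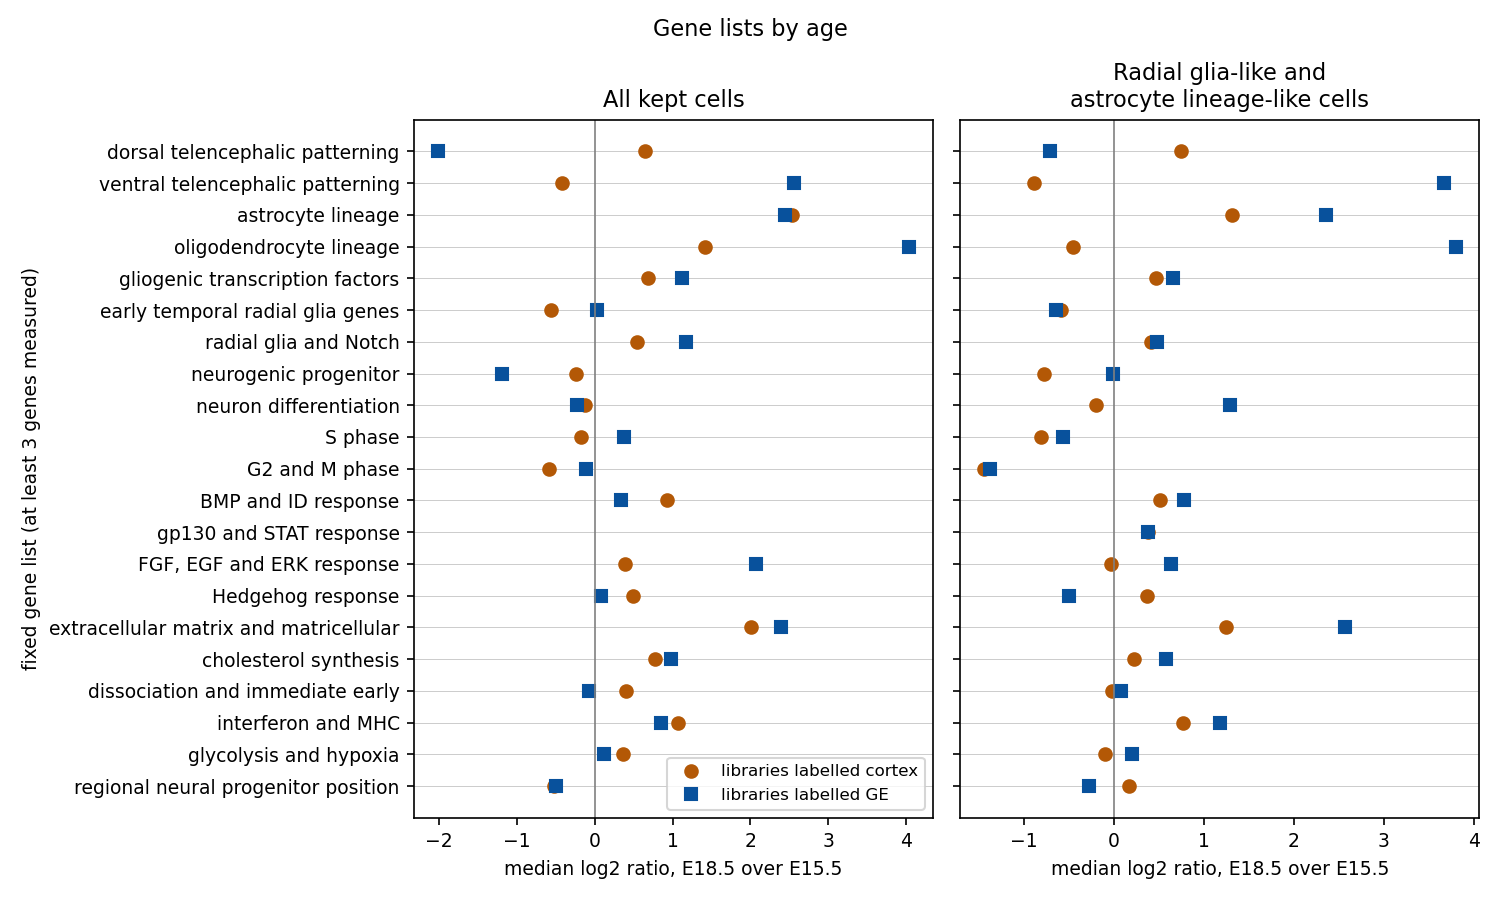
Median log2 ratio of E18.5 to E15.5 for each fixed list with at least 3 measured genes, in all kept cells and in the pooled radial glia-like and astrocyte lineage-like cells, with circles for libraries labelled cortex and squares for those labelled GE. The astrocyte list lies at 2.53 and 2.45 in all cells, and the ventral list at -0.42 and 2.56.

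The libraries labelled cortex and GE were compared at each age to see how the regions differ. Genes of the opposite region to the label stood out in both directions. Nkx2-1 was 269-fold (179 to 425) higher in the library labelled cortex at E15.5 and 62.1-fold (40.5 to 100.5) higher at E18.5, with a log2 ratio of 8.76 in place of 8.07 at E15.5 in thinned cells. Six3, a transcription factor of striatal progenitors, was 66.4-fold and 24.2-fold higher, and Gsx1, a ventral progenitor factor, 129-fold and 5.20-fold. Neurog2, the proneural factor of cortical progenitors, was 142-fold (124 to 163) lower in the library labelled cortex at E15.5 and 48.1-fold (39.5 to 59.1) lower at E18.5. Eomes, which marks cortical intermediate progenitors, was 180-fold (143 to 229) and 43.8-fold (34.8 to 55.8) lower, and Emx1 (chromosome 6, 85187438 to 85204462) was 215-fold (149 to 321) and 31.6-fold (21.4 to 48.6) lower. In thinned cells the log2 ratio at E15.5 was 6.73 in place of 6.05 for Six3 and -8.68 in place of -7.75 for Emx1. That of Gsx1 at E15.5 was 6.35 in place of 7.01, and that of Neurog2 at E18.5 -6.42 in place of -5.59. Dlx2 (chromosome 2, 71543408 to 71546754), which drives GABAergic fate, had 996 and 773 CPM in the libraries labelled cortex E15.5 and E18.5, and 23.5 and 187 CPM in those labelled GE.

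Of 7074 genes measured at both ages, 91 were higher in the libraries labelled cortex at both and 123 were lower, so 42.5% of the 2 sets together were higher in the libraries with that label. If the labels were exchanged, the 2 counts would change places. The other 7 of the 10 named higher genes were Nkx2-3, Slc18a2, Asb4, Stk32c, Vax1, Zfhx3 and Slit1. The other 7 lower genes were Tfap2c, Neurod6, Nrn1, Tmem132b, Dmrta2, Fezf2 and Sstr2. TMM scaling moved every log2 ratio by 0.12 at E15.5 and 0.16 at E18.5, and then 144 genes were higher and 95 lower, or 60.3% higher. At E15.5 alone 383 genes were higher and 445 lower of 7403, and at E18.5 113 higher and 286 lower of 7797.

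Cell cycle genes differed beside patterning genes, mainly at E15.5. Of 20 S phase genes, 14 were higher at E15.5 (median 1.14) and 4 at E18.5 (median 0.58), and of 20 G2 and M phase genes 15 (median 1.19) and 5 (median 0.69). Top2a, a topoisomerase of dividing cells, had log2 ratios of 1.90 and 1.16, and the replication factor Cdc6 had 2.00 and 1.17. In radial glia-like and astrocyte lineage-like cells alone, both lists had medians on the other side of 0 at both ages, -0.35 and -0.69 for S phase and -0.61 and -0.91 for G2 and M phase. Of oligodendrocyte lineage genes at E18.5, 9 of 10 were lower (median -1.98), with Pdgfra, the growth factor receptor of their precursors, at -2.53, while at E15.5 2 of 4 were higher (median 1.28). Astrocyte lineage genes were lower for 6 of 17 and higher for 1 at E15.5 (median -0.84), with the metallothionein gene Mt2 at -2.01, and lower for 5 of 24 at E18.5 (median -0.44). Genes of the extracellular matrix were lower for 3 of 9 and higher for 1, then lower for 5 of 11, with the growth factor gene Ptn at -1.61 and -1.40. The share of oligodendrocyte lineage-like cells was also lower in the library labelled cortex E18.5.

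Gliogenic transcription factors were lower for 6 of 13 and higher for 3 at E15.5, and lower for 5 of 15 at E18.5 (median -0.74), with Hopx, a factor of outer radial glia, at -4.12 at E18.5 and Nfix at -1.82 at E15.5. The radial glia and Notch list had 2 of 18 higher and 2 lower, then 2 of 19 lower (median -0.59), with Pax6 at -2.85 and -1.96. Regional position genes were lower for 6 of 13 and higher for 4, then lower for 6 of 14 and higher for 2, including Fezf2 at -6.37 and -3.60. The neurogenic progenitor list had 7 of 16 lower and 2 higher, then 3 of 13 lower, and neuron differentiation genes 4 of 19 lower and 4 higher, then 3 lower and 3 higher. Hedgehog response genes were lower for 3 of 7 and higher for 1, then lower for 2 of 5, with the co-receptor gene Cdon at -2.79 and -2.51. BMP and ID response genes were lower for 2 of 6 and higher for 1, then lower for 2 of 6, with Id2 at -2.92 and -1.46.

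Smaller sets followed. FGF, EGF and ERK response genes were lower for 1 of 6, then 4 of 12 (median -0.79), with Spry4 at -1.64 at E18.5. Cholesterol synthesis genes had 0 of 17 past 2-fold, then 3 of 18 lower (median -0.76), among them Hmgcs1 at -1.12. Early temporal genes were higher for 3 of 10, then lower for 1 of 8, with H19 at 2.80 at E15.5. Immediate early genes were lower for 3 of 8, then 0 of 8, with Jun at -1.12 at E15.5. Interferon and MHC genes were lower for 1 of 3 (Ifitm2, -1.97), then 0 of 5. Glycolysis and hypoxia genes were lower for 2 of 12, with Ndrg1 at -4.41, then 2 of 13, with Egln3 at -1.86. Stat3 was the 1 gene past 2-fold of the gp130 and STAT response list, at -1.11 at E18.5.

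Vascular genes were also lower in the libraries labelled cortex. The endothelial genes Cldn5, Igfbp7 and Itm2a were all lower at E15.5 (median -6.58), Cldn5 with 2 UMIs against 955, and 3 of 3 were lower at E18.5 (median -1.15). The pericyte gene Rgs5 had log2 ratios of -5.02 and -2.71, and 3 of 5 mural genes were lower at E18.5 (median -1.68, or -0.91 with TMM). Mural cell-like barcodes were likewise fewer in these libraries. None of 4 erythroid genes differed 2-fold at E15.5. Enpp2 was lower at E18.5 (-2.28).

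To narrow the mix of cells, UMIs were summed over radial glia-like and astrocyte lineage-like cells alone, called the pooled glial cells below. The libraries labelled cortex E15.5, cortex E18.5, GE E15.5 and GE E18.5 gave 26, 631, 97 and 423 such cells, of which 24, 614, 2 and 218 were astrocyte lineage-like. The mix of the 2 classes thus changes with age in those labelled GE and differs between labelled regions, and the classes were named by markers that stand in the lists. Clusters 4 and 6 gave most of those labelled cortex, cluster 18 most of those labelled GE E15.5, and clusters 13 and 4 most of those labelled GE E18.5. Cell division genes were lower at E18.5 in both labelled regions, whereas 0 of 20 G2 and M phase genes passed 2-fold in whole libraries. Clusters 8, 10, 11 and 12, with histone or cell division genes among their top genes, lie outside the pool. The levels of such genes in the pool thus depend on the clustering. Ube2c, which drives exit from mitosis, was 4.98-fold (4.32 to 5.74) lower in those labelled cortex and 4.11-fold (3.79 to 4.47) lower in those labelled GE. The mitotic kinase gene Aurka was 4.59-fold and 3.73-fold lower, and Cdc20 4.58-fold and 2.97-fold. Of 20 G2 and M phase genes, 16 were lower (median -1.44) and 13 were lower (median -1.37), and of 19 S phase genes 5 (median -0.81) and 1 (median -0.57). Neurog2 was 37.4-fold (18.7 to 81.4) and 3.01-fold (2.73 to 3.31) lower. Its size in those labelled cortex depends on processing. The log2 ratio of -5.23 became -6.91 with the filter of at least 2000 genes, -7.12 in thinned cells and -8.12 with radial glia-like clusters only.

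Astrocyte genes were higher with age in these pooled cells. In those labelled GE the share of astrocyte lineage-like cells was larger at E18.5, which may set part of this and was not tested. In those labelled cortex that share was high at both ages, but its clusters shifted. Cluster 4 held 14 and cluster 6 held 10 of 26 pooled cells at E15.5, against 251 and 363 of 631 at E18.5. The 14 barcodes had a median of 26422.5 UMIs, against 16249 in that whole library. Apoe was 7.05-fold (6.37 to 7.81) and 21.5-fold (17.6 to 26.5) higher. Aqp4 was 27.1-fold (7.48 to 225) higher in those labelled cortex, on 2 UMIs at E15.5, and 14.9-fold (6.31 to 46.1) higher in those labelled GE. Luzp2, a gene of astrocyte precursors, was 6.89-fold and 6.49-fold higher. With radial glia-like clusters only, the log2 ratios of Apoe, Aqp4 and Sparcl1 in those labelled GE were 3.68, 2.70 and 2.71. They stood in place of 4.42, 3.89 and 3.65. That setting compares mostly cluster 18 at E15.5 with cluster 13 at E18.5. Astrocyte markers had mean log2 folds of -0.47 and 0.97 in these clusters. The clusters were made from this same expression, so the ratios cannot tell a change within a class from the mix. Of 24 astrocyte lineage genes 16 were higher in those labelled cortex (median 1.31) and 18 of 25 in those labelled GE (median 2.36), the glutamate transporter gene Slc1a2 at 2.40 and 6.71. Ependymal genes were higher too in those labelled cortex, for 5 of 5 (median 1.80), and cluster 6, where astrocyte markers had a mean log2 fold of 2.06, had ependymal markers next at 1.67. Genes of the extracellular matrix were higher for 6 of 11 (median 1.25) and 9 of 10 (median 2.57), with the proteoglycan gene Vcan at 1.31 and 3.32. Sparcl1 had 2.58 and 3.65, and Sparc had 1.71 in those labelled GE and was just under 2-fold in those labelled cortex. Early temporal genes were lower for 2 of 8 (median -0.59) and 3 of 9 (median -0.65), with Igf2bp1 at -1.44 and -1.05. Hmga2, a chromatin factor of early stem cells, was lower at -2.75 in those labelled GE and was under the CPM minimum in those labelled cortex.

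Among 7367 genes, 318 were higher and 73 lower at E18.5 in both labelled regions, so 81.3% of these were higher. With size factors from DESeq2 221 were higher and 111 lower, or 66.6% higher. TMM scaling moved the log2 ratios by -0.12 in those labelled GE and by under 0.1 otherwise. With radial glia-like clusters only, which leave 2 cells in the library labelled cortex E15.5, 30 genes were higher and 10 lower, 12 and 2 of them among the genes above, and Ube2c and Ccnb1 turned in those labelled cortex, to 0.53 and 1.71. Thinned to 1 depth per cell, 178 were higher and 61 lower, 116 and 40 of them among the genes above. The remaining named genes were Kcnk1, Slco1c1, Entpd2, Gabrb1, AY036118, Nwd1 and Cldn10, all higher, and Arhgef39, Kif20a, Ccnb1, Plk1, Ccnf and Ccna2, all lower. Gabrb1 and Kcnk1 rest on 1 UMI each in the library labelled cortex E15.5, with intervals of 6.38 to 1420 around 35.8-fold and of 4.45 to 990 around 25.0-fold. In thinned cells labelled cortex their log2 ratios fell to 1.45 and 0.87, and that of Nwd1 from 2.97 to 0.25.

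Oligodendrocyte lineage genes of the pooled glial cells were higher at E18.5 for 1 of 5 in those labelled cortex (median -0.45) and for 6 of 6 in those labelled GE (median 3.80), with Olig1 at -0.45 and 4.14. Ventral patterning genes were lower for 4 of 12 (median -0.89) and higher for 8 of 9 (median 3.67, with 2 at their bound). Radial glia and Notch genes were higher for 3 of 19 and lower for 2 in those labelled cortex (median 0.41), and higher for 6 of 19 in those labelled GE (median 0.48), with Notch2 at 2.00 and 0.78. Gliogenic factors were higher for 4 of 16 and lower for 1, and higher for 4 of 15, with Nfia, which switches progenitors to astrocyte production, at 1.52 and 0.77. Neuron differentiation genes were higher for 2 of 13 and lower for 2, but higher for 10 of 16 in those labelled GE (median 1.29), with the microtubule-associated gene Mapt at 2.42 and 1.56. Neurogenic progenitor genes were lower for 5 of 12 (median -0.77), and 2 were higher and 2 lower of 13. FGF, EGF and ERK response genes had 0 of 11 past 2-fold and 5 of 11 higher (median 0.63), with Egfr at 0.43 and 5.23. Cholesterol synthesis genes had 0 of 18 past 2-fold in each. BMP and ID response genes were higher for 1 of 7, and higher for 3 and lower for 1 of 7.

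Patterning genes also differed between labelled regions in the pooled glial cells, the ventral ones mainly at E15.5. Nkx2-1 was at least 34.0-fold higher in the library labelled cortex at E15.5, against 0 UMIs, and 41.5-fold (17.5 to 129) higher at E18.5. Six3 was 16.9-fold (6.47 to 55.9) and 29.1-fold (18.7 to 48.1) higher. Emx1 was at least 16.4-fold lower at E15.5, against 0 UMIs, and 18.55-fold (10.4 to 36.4) lower at E18.5, and Dmrta2, a factor of cortical neuroepithelium, 15.2-fold and 8.58-fold lower. Of 11 dorsal genes 11 were lower at E15.5 (median -2.77, with 4 genes at their bound) and 8 of 10 at E18.5 (median -4.77). Ventral genes were higher for 11 of 12 at E15.5 (median 3.81, with 4 at their bound), and at E18.5 2 of 11 were higher and 1 lower (median 0.58).

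Astrocyte genes had medians above 0 in the pooled cells labelled cortex, where whole libraries had medians below 0. More of the cells labelled cortex were astrocyte lineage-like, so class make-up may set part of this, which was not tested. Of 23 astrocyte lineage genes 13 were higher at E15.5 (median 1.26) and 9 of 25 at E18.5 (median 0.81), and at E18.5 ependymal genes were higher too, for 5 of 5 (median 2.40). Apoe had 3.52 and 1.91, and Slc1a2 5.45 and 1.14. Genes of the extracellular matrix were higher for 8 of 10 at E15.5 (median 1.39) and 3 of 11 at E18.5, with Vcan at 3.08 and 1.07. G2 and M phase genes were lower for 3 of 20 (median -0.61) and 9 of 20 (median -0.91), with the kinesin gene Kif11 at -1.21 and -1.44, and S phase genes for 0 and 1 of 19. Neurogenic progenitor genes were lower for 5 of 14 and higher for 2, then lower for 8 of 12 (median -1.48), with Insm1, a factor of basal progenitors, at -2.47 and -1.97. Oligodendrocyte lineage genes were higher for 4 of 5 at E15.5 (median 3.13), and at E18.5 2 were lower and 1 higher of 6, with Pdgfra at -3.99. At both ages these cells came from different clusters in the 2 libraries.

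In all, 115 genes were higher and 50 lower in the pooled cells labelled cortex at both ages, of 7148. The other named higher genes were Nkx2-3, Nkx6-2, Sfrp5, Timp4, Tekt1, Spon1, Ildr2 and Meg3, and the other lower ones Tfap2c, Neurod6, Fezf2, Cdon, Neurog2, Etl4, Dct and Eomes. Tekt1, which encodes a protein of cilia, was 10.7-fold (2.82 to 59.6) higher at E15.5 and 6.47-fold higher at E18.5. Dct had 0 UMIs in both libraries labelled cortex and was at least 6.29-fold and at least 54.6-fold lower. The 26 pooled cells of the library labelled cortex E15.5 hold 434254 UMIs, so 0 UMIs there allow a level of up to 6.91 CPM. With radial glia-like clusters only, which leave 2 of those cells, 18 genes were higher and 6 lower, 9 and 0 of them among the genes above, and Neurog2, Tfap2c, Dmrta2 and Eomes turned at E15.5, as did Dcx at E18.5.

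Age ratios that differ between labelled regions could come from programmes that switch in 1 region only, or from changes in the cell mix. Across whole libraries no gene passed 2-fold in opposite directions, and lists were compared over the genes measured in both, a choice made after seeing the data. All 9 such ventral genes had the lower age ratio in the libraries labelled cortex (medians -0.37 and 2.56, median difference -2.91), and so did all 5 such oligodendrocyte lineage genes (medians 1.42 and 4.16, median difference -2.74). Only 3 dorsal genes were measured in both, all with the higher age ratio in those labelled cortex (medians 0.64 and -0.76, median difference 1.21). In libraries labelled GE, oligodendrocyte lineage-like cells went from 0.460% to 25.9% and GE intermediate progenitor-like cells from 0.805% to 7.48%. In those labelled cortex they went from 0.432% to 5.62% and from 51.4% to 45.8%. GABAergic neuron-like cells had larger shares at E18.5 in both. The cell mix may thus set part of these differences, which was not tested. In the pooled glial cells 13 genes went opposite ways. Dlx1 and Dlx5, GABAergic fate genes, had log2 ratios of -1.12 and -1.29 in those labelled cortex and 3.68 and 3.78 in those labelled GE. Id4, an inhibitor of neuronal differentiation, was higher in those labelled cortex (1.20) and lower in those labelled GE (-1.17), and the neuronal tubulin gene Tubb3 had -1.09 and 1.18. The differences between the age ratios have no test.

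Sparc and Sparcl1, 2 related matricellular genes, were read per cell because the title of the series speaks of divergent astrocyte lineages. Sparc lies on chromosome 11 (55394500 to 55423183) and Sparcl1 on chromosome 5 (104079111 to 104113733). In pooled glial cells thinned to 5000 UMIs, Sparc was detected in 68.8% (64.7 to 72.7) and Sparcl1 in 43.9% (39.6 to 48.2) of 529 cells labelled cortex E18.5. In 401 cells labelled GE E18.5 the shares were 50.9% (45.9 to 55.9) and 57.1% (52.1 to 62.0). Both genes were detected together in 26.3% (22.6 to 30.2) of the cells labelled cortex E18.5, where independent detection gives 30.2%, a ratio of 0.871 (0.801 to 0.935 with cells resampled). For the cells labelled GE E18.5 the values were 24.4% (20.3 to 28.9) and 29.1%, a ratio of 0.841 (0.755 to 0.924). With the expected share held fixed the intervals were 0.748 to 1.002, which includes 1, and 0.699 to 0.996. Resampling was chosen after seeing the data, since the expected share has error too. These ratios pool clusters that differ in detection of the 2 genes, which are read apart below. At E15.5 Sparc was detected in 57.7% of 26 cells labelled cortex and 39.2% of 97 labelled GE, and Sparcl1 in 23.1% and 9.28%.

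The E18.5 shares lie above the level in a cell type that should lack both genes. In GABAergic neuron-like cells thinned alike, Sparc and Sparcl1 were detected in 3.14% and 2.00% of 350 cells labelled cortex E18.5, and in 1.79% of 112 cells labelled GE E18.5 for each. At E15.5 only 41 and 1 such cells were kept, so no level is given for that age. Their median depth before thinning was 5138.5 and 5436 UMIs, against 8334 and 12154 in the pooled glial cells. Thinning left out 102 pooled cells labelled cortex E18.5, 22 labelled GE E18.5 and none at E15.5, and 302 and 42 GABAergic neuron-like cells. Without thinning, Sparc was detected in 75.6% and Sparcl1 in 52.5% of the cells labelled cortex E18.5, and in 63.8% and 72.1% of those labelled GE E18.5, with resampled ratios of 0.939 (0.897 to 0.981) and 0.914 (0.869 to 0.957) for joint detection. With the expected share held fixed these intervals were 0.844 to 1.04 and 0.811 to 1.02, which include 1. With detection set at 2 UMIs in thinned cells, the ratios were 0.755 (0.638 to 0.870) and 0.653 (0.502 to 0.806), and both kinds of interval exclude 1.

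**Figure D4:**
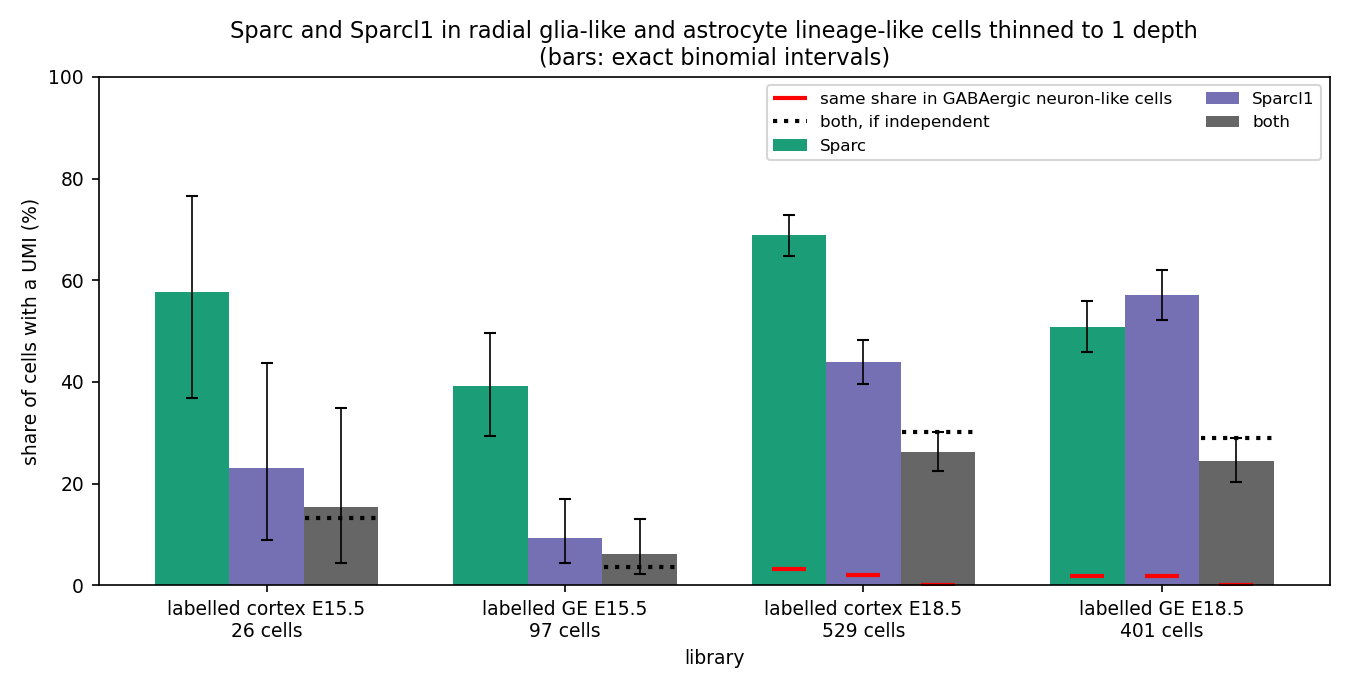
Share (%) of pooled glial cells, thinned to 5000 UMIs, with a UMI of Sparc, of Sparcl1 and of both in the 4 libraries, with exact binomial 95% intervals, the share expected from independence (dotted) and the share in GABAergic neuron-like cells (red dashes, E18.5). Both were detected together in 26.3% and 24.4% of cells labelled cortex E18.5 and GE E18.5, where independence gives 30.2% and 29.1%.

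The clusters differed in which of the 2 genes was detected more often. In cluster 4, Sparcl1 was detected in 75.0% and Sparc in 38.5% of 200 cells labelled cortex E18.5, and in 83.6% and 25.5% of 165 labelled GE E18.5. In cluster 6, Sparc was detected in 87.3% and Sparcl1 in 23.7% of 316 cells labelled cortex E18.5. In cluster 13, they were detected in 65.1% and 43.1% of 195 cells labelled GE E18.5. The ratio of joint to independent detection with cells resampled was 1.14 (1.05 to 1.25) and 1.14 (1.05 to 1.23) in cluster 4, 1.04 (0.968 to 1.11) in cluster 6 and 0.951 (0.825 to 1.07) in cluster 13. With the expected share held fixed all 4 intervals include 1. In the 13 cells of cluster 13 labelled cortex E18.5 the ratio was 0.844 (0.304 to 1.502 with the share held fixed). Within these clusters joint detection was thus not below independent detection beyond its interval. The ratios below 1 in the pooled cells therefore do not show that the 2 genes avoid each other within a cluster. Sparcl1 is 1 of the markers that name the astrocyte lineage class, so its share in these clusters is partly set by their naming.

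Cells with Sparc alone and cells with Sparcl1 alone differed in other genes, but came mostly from different clusters. In those labelled cortex E18.5, cluster 6 held 208 of 225 Sparc-only cells and cluster 4 held 84 of 93 Sparcl1-only cells. In those labelled GE E18.5, clusters 13 and 6 held 75 and 27 of 106 Sparc-only cells. Cluster 4 held 98 of the 131 Sparcl1-only cells there. The genes below thus largely compare clusters, which were made from the expression of these same cells. Of 7652 genes measured in both E18.5 libraries, 207 were at least 2-fold higher in Sparc-only cells in both and 140 in Sparcl1-only cells in both. The genes named here were chosen after their values were seen. Tppp3, a gene of ciliated cells, was 24.3-fold (9.36 to 89.9) higher in Sparc-only cells labelled cortex E18.5 and 11.1-fold (4.43 to 35.9) higher in those labelled GE E18.5, and the imprinted RNA gene H19 was 11.0-fold higher in each. In Sparcl1-only cells Serpine2, a secreted protease inhibitor gene, was 11.6-fold (8.65 to 15.7) and 10.4-fold (6.74 to 16.9) higher, the ERK feedback gene Spry1 7.40-fold and 10.2-fold, and the glutamate receptor gene Grm5 15.9-fold and 9.50-fold. Of the FGF, EGF and ERK response genes, 8 of 11 and 7 of 12 were higher in Sparcl1-only cells (medians -1.44 and -1.56 as Sparc-only over Sparcl1-only), and 1 in each library was higher in Sparc-only cells. Astrocyte lineage genes split both ways, with 8 of 23 higher in Sparc-only and 5 in Sparcl1-only cells labelled cortex E18.5 (median 0.52), and 9 and 4 of 23 in those labelled GE E18.5 (median 0.06). Immediate early genes, which dissociation can induce, were higher there too, for 8 of 14 (median -1.77) and 5 of 11 (median -0.41). G2 and M phase genes were higher there for 17 of 18 in cells labelled cortex E18.5 (median -2.08) and 2 of 20 in those labelled GE E18.5 (median -0.56). Ependymal genes were higher in Sparc-only cells for 5 of 5 (median 4.32) and 2 of 2.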

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

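The test of tissue carried over in dissection was chosen only after its result was seen. Each result below was taken up because the same contrast went opposite ways in the 2 labelled regions or at the 2 ages, and with 1 library per group none of these differences was tested.

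With age, 2 of 16 ventral patterning genes were lower in whole libraries labelled cortex (median log2 ratio -0.42) and 9 of 9 higher in those labelled GE (2.56), while 0 of 3 dorsal genes passed 2-fold (0.64) and 11 of 13 were lower (-2.02). In the pooled glial cells the ventral list had -0.89 and 3.67. The same cells gave Dlx1 at -1.12 and 3.68, Dlx5 at -1.29 and 3.78, Dll3, a Notch ligand of ventral progenitors, at -1.15 and 3.77, and Nxph1 at -1.07 and 2.30. The dorsal and ventral genes fit exchanged region labels, under which the library labelled GE E18.5 holds cortex. If that library holds cortex, ventral tissue carried over in dissection would bring its patterning factors in their own ratios. Nkx2-1, Lhx8, Isl1 and Six3 together reached 11.1% (8.75 to 14.0) of the level that Dlx1, Dlx2, Gad1 and Gad2 imply there, which argues against carried-over tissue of that make-up as the whole source. Nkx2-1 had 21 UMIs there and Dlx2 had 2139. GABAergic neuron-like cells made up 0.115% and 13.5% of the libraries labelled GE E15.5 and E18.5. At E18.5 cluster 16 held 132 of these 154 cells, against 35 of 652 labelled cortex. The ratio thus cannot tell a smaller amount of carried-over tissue beside these cells from none. A biological difference between the ages stays open and untested.

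Other genes of the pooled glial cells with opposite age ratios, labelled cortex first, were as follows. Those lower in the cells labelled cortex were Nab2 at -1.66 and 1.77, Tubb3 at -1.09 and 1.18, Ubash3b at -1.28 and 1.49, and Nell2 at -1.54 and 1.12. Prr18 at -1.28 and 3.73, Zfp57 at -1.35 and 1.28 and Eno1b at -1.19 and 1.05 went the same way. Shisa2, an FGF and Wnt receptor inhibitor, was higher in the cells labelled cortex at 2.41 and lower in those labelled GE at -2.92, and Id4 had 1.20 and -1.17. Of the pooled cells labelled GE, 2 of 97 at E15.5 and 218 of 423 at E18.5 were astrocyte lineage-like, so their age ratios move with that mix.

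Between labelled regions, 5 genes of whole libraries were higher in the library labelled cortex at E15.5 and lower at E18.5. They were Id3 at 1.01 and -1.31, Nxph1 at 1.05 and -1.11, Lrrn1 at 1.40 and -1.05, Olig2 at 3.35 and -1.20, and Sox8 at 1.64 and -1.05. The oligodendrocyte lineage list had 1.28 and -1.98, and the early temporal list 0.29 and -0.41. In the pooled glial cells Lhx6 had 3.42, a bound against 0 UMIs, and -1.32, Dcx 1.01 and -1.54, Dll3 3.39 and -1.54, and Zfp57 1.18 and -1.45. There the oligodendrocyte lineage list had 3.13 and -0.45, and the neuron differentiation list 0.62 and -0.42.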

How the results depend on the processing

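The alternatives without the deepest barcodes, the resampled intervals and the list medians over shared genes were chosen only after the results were seen. Over 338 results, 2937 alternative values were computed, of which 2429 stayed within the set limits, 485 moved beyond them and 23 reversed. Of the log2 ratios of named genes, 97 of 500 by age and 63 of 595 by region moved in whole libraries, and 69 of 632 and 67 of 630 in pooled glial cells. Other CPM minimums and fold thresholds leave these log2 ratios as they are, so those values could not move and lower the shares that did. With thinned cells alone, 22 of 40 by age and 22 of 48 by region moved in whole libraries. In pooled glial cells 18 of 47 moved in each.

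For genes by age in whole libraries (234 higher, 9 lower), a minimum of 5 CPM gave 544 and 22, 100 CPM gave 54 and 5, and no minimum 1216 and 62. A 1.5-fold threshold gave 616 and 70, and 3-fold 92 and 4. Genes lower numbered 16 with DESeq2 scaling, 5 without the cell filter and doublet removal, 5 with the strict filter and 1 without the deepest barcodes. Genes with opposite age ratios (0) numbered 1 with DESeq2, 14 at 5 CPM, 58 with no minimum, 16 at 1.5-fold, 1 by the mean of cells and 1 with thinned cells. Of 170 genes higher with TMM, 170 were among the 234. Without the cell filter and doublet removal, which were left out together, the haemoglobin genes reversed in the libraries labelled GE, Hbb-bt to 0.24, Hba-a2 to 0.29, Hba-a1 to 0.46 and Hbb-bs to 0.23. With all barcodes the libraries labelled GE E15.5 and E18.5 held 52764 and 32288 haemoglobin UMIs, and the kept cells 14652 and 93.

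For genes by region in whole libraries (91 higher, 123 lower), TMM gave 144 higher and DESeq2 146. A minimum of 5 CPM gave 288 lower, 100 CPM 28 higher and 20 lower, and no minimum 228 and 662. Thresholds of 1.5-fold and 3-fold gave 294 and 291, and 25 and 53.

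In pooled glial cells by age (318 higher, 73 lower), DESeq2 gave 111 lower, 100 CPM 72 and 26, 1.5-fold 714 and 303, and 3-fold 91 and 7. Thinned cells gave 178 higher, and radial glia-like clusters only 30 and 10. Genes with opposite age ratios (13) numbered 32 at 5 CPM, 2 at 100 CPM, 34 with no minimum, 61 at 1.5-fold, 2 at 3-fold, 22 with the strict filter and 20 with radial glia-like clusters only. By region (115 higher, 50 lower), 5 CPM gave 206 higher, no minimum 216 higher, 100 CPM 22 and 15, 1.5-fold 260 and 172, 3-fold 37 and 22, and radial glia-like clusters only 18 and 6. With those clusters only, Ube2c reversed to 0.53 and Ccnb1 to 1.71 by age in cells labelled cortex. Neurog2 reversed to 1.85, Tfap2c to 0.96, Dmrta2 to 0.31 and Eomes to 2.12 by region at E15.5, and Dcx to 0.72 at E18.5. That setting leaves 2 cells labelled cortex E15.5, so its ratios at E15.5 rest on few cells.

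The dorsal list stayed lower and the ventral list higher in the libraries labelled cortex under every alternative run. In pooled glial cells the dorsal medians were -2.77 at E15.5 and -4.77 at E18.5 and the ventral ones 3.81 and 0.58. Without the deepest barcodes the dorsal median at E15.5 was -6.53, and the ventral ones 4.95 and 1.57. TMM moved the ventral median at E18.5 to 1.98. With TMM, 80 of 87 list medians stayed within 0.5 on the same side of 0, 1 moved further (mural genes by region at E18.5, -0.91 in place of -1.68), and 6 that lay near 0 changed sign. These were early temporal, glycolysis and Hedgehog genes by age in libraries labelled GE, neuron differentiation and interferon genes by region at E15.5, and immediate early genes by region at E18.5. A change of sign counts as a reversal only where the median lay outside the middle 95% of random lists, which left 0 with TMM. In pooled glial cells 31 of 80 changed sign, of which 12 lay outside the middle 95% of random lists in both sets of cells and are given here. Of the others, oligodendrocyte genes by age in those labelled cortex had -0.45 in place of 1.42, and neuron differentiation genes by age in those labelled GE 1.29 in place of -0.23. By age in libraries labelled GE, S phase had -0.57. By region at E15.5, astrocyte genes had 1.26, radial glia and Notch 0.53, S phase -0.35, G2 and M phase -0.61, extracellular matrix 1.39 and cholesterol 0.36. By region at E18.5, astrocyte genes had 0.81, radial glia and Notch 0.26, S phase -0.69, G2 and M phase -0.91 and extracellular matrix 0.24. The setting leaves out other cell classes, and the cause of single reversals was not tested.

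Astrocyte lineage-like cells labelled cortex E18.5 made up 15.9% at resolution 2 and 22.4% with thinned cells, and radial glia-like ones 3.07% and 0.326%. For those labelled GE E18.5 the shares were 11.8% and 22.5%, and 25.4% and 12.3%, with 13.1% radial glia-like cells without the deepest barcodes. The cause was not tested. Joint detection of Sparc and Sparcl1 in cells labelled GE E18.5 had a ratio of 0.616 at 2000 UMIs and 0.653 at 2 UMIs per gene. For cells labelled cortex E18.5 these were 0.837 and 0.755. With cells resampled, the ratio of 0.871 for the latter cells had an interval of 0.801 to 0.935 in place of 0.748 to 1.002. Over genes measured in both labelled regions, the dorsal age medians were 0.64 and -0.76 on 3 genes, in place of 0.64 and -2.02. Genes between Sparc-only and Sparcl1-only cells numbered 103 and 87 at 2000 UMIs, where fewer UMIs are left to call them. Depth limits the cells labelled cortex E15.5 most, where 26 pooled cells set a floor of 6.91 CPM.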

Other observations

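The test of depth for the deep barcodes was chosen only after its result was seen. Within the pooled glial cells, genes of ciliated ependymal cells were higher at E18.5 in those labelled cortex, for 5 of 5 measured (median log2 ratio 1.80). Foxj1, the master regulator of motile cilia, had 1.39, and Meig1 had 3.27 on 1 UMI at E15.5. In those labelled GE only Foxj1 was measured, at 2.72. Otx2, a transcription factor of midline and choroid tissue, had 2.33 by age in those labelled cortex and 4.72 between labelled regions at E18.5.

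Among signalling and stress lists of the pooled glial cells, Hedgehog response genes had 0 of 5 past 2-fold with age in those labelled cortex and 1 of 7 higher in those labelled GE, Ptch1 at 1.22. Between labelled regions Ptch1, the receptor and target gene, was higher at 2.47 and 1.07, while Cdon at -5.00 and -2.91 and Gas1 at -2.27 and -1.16 were lower. Of the gp130 and STAT response genes, Il6st was higher with age in those labelled cortex (1.34) and Stat3 in those labelled GE (2.01). Interferon and MHC genes were higher for 1 of 5 and 3 of 5, with Ifitm3 at 1.49 and 4.06. Vegfa, a growth factor of vessels, was higher at 2.51 and 1.82, although glycolysis and hypoxia genes as a list had medians of -0.10 and 0.20. Immediate early genes had medians of -0.02 and 0.08, with Fos at 1.60 and 1.25. The pericyte receptor gene Pdgfrb was higher with age at 1.56 and 1.90. The fibroblast gene Ogn was higher in those labelled cortex at 2.98.

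The labels and the file names disagree on region for all 4 libraries. An exchange of the region labels at both ages predicted lower dorsal and higher ventral genes in the libraries labelled cortex. The dorsal list had medians of -6.08 (-6.47 to -5.65) and -3.92 (-4.11 to -3.74), and the ventral list 5.21 (5.03 to 5.37) and 1.82 (1.71 to 1.89), with intervals from 1000 draws. These values are consistent with exchanged labels. A difference between regions as labelled would have put dorsal genes higher in the libraries labelled cortex, which they were not. No region was reassigned.

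In the E15.5 libraries, barcodes over 2 times the median depth held 46.5% and 50.1% of the UMIs of those labelled cortex and GE, and clusters 7 and 2 each held barcodes of mostly 1 library. If depth alone made these clusters, thinning would spread them, but 75.0% (70.4 to 79.3) of 384 and 67.7% (63.5 to 71.7) of 514 still shared 1 cluster after thinning. Of the other barcodes of these libraries, those outside clusters 2 and 7, 1.69% and 31.7% lay in the same cluster. The shares argue against depth as the whole cause, less strongly in the library labelled GE E15.5, where other barcodes joined that cluster too. If barcodes held more than 1 cell of pooled male and female embryos, deep ones would more often carry both Xist and Y-linked UMIs. After thinning to 10000 UMIs, 42.3% (37.3 to 47.4) of the deepest barcodes labelled cortex E15.5 and 46.6% (40.7 to 52.5) of those labelled GE E15.5 carried both, against 6.48% and 14.8% of the shallowest, each set being the third of its library ranked by UMIs. In cluster 7 labelled cortex E15.5 the share with both was 43.0% (38.0 to 48.1), where independent detection gives 45.0%. In cluster 2 labelled GE E15.5 it was 40.1% (35.8 to 44.5) against 44.2%. In E18.5 barcodes of at least 10000 UMIs it was 6.38% labelled cortex and 14.4% labelled GE. These values argue against 1 cell per barcode for many barcodes of these clusters. A true cell state of E15.5 in the rest stays open and untested.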
